A study of Mus musculus with 59 samples.

How the data were processed

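The deposited table held whole-number read counts per OTU, a cluster of similar 16S rDNA sequences that stands for a bacterial taxon, in colon samples of ICR mice aged 10 weeks. Per the labels, colon contents were taken out quickly, the tissue was frozen in liquid nitrogen, total DNA was extracted and 16S rDNA libraries were sequenced on an Illumina HiSeq. The tool that clustered reads into OTUs, the similarity threshold, chimera removal and the amplified 16S region were not given in the sources used here. The submitters' processing notes name the mouse build mm10 without stating its role. The deposited counts were raw, not scaled to a common depth: library totals ran from 32134 to 63470 reads. The table listed 1630 OTUs, of which 1487 had a read in the 59 libraries analysed. A further 80 columns of the table matched no sample in the labels and were not used here. The table gave OTU numbers without taxa or sequences, so the files do not pair OTU IDs with taxa. Tests at genus level, phylum shares, the lists of bacterial genera fixed before the data were examined, and the alternatives that would remove reagent or diet DNA were therefore not run, and the OTU was the level of analysis, as laid down for that case before the data were examined.

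Samples were grouped by the treatment in their labels into control (n = 10), AOS (n = 10), high fat diet (HFD, n = 10), HFD+AOS (n = 10), HFD+AOS-FMT (n = 9) and HFD+control-FMT (n = 10). The labels give AOS at 10 mg/kg for AOS, HFD+AOS and HFD+AOS-FMT, and no dose for HFD+control-FMT. They do not say whether the dose of HFD+AOS-FMT was given to donors or to recipients, and do not spell the abbreviation out. FMT stands for a transfer of gut microbiota. Neither the donors, the housing nor the timing of the transfers was given in the sources used here, so cages may be shared within a group. The tests set group differences against the spread between libraries and take libraries as independent. If cages were shared within a group, the p-values would tend to be too small. Libraries are named by group and by the number in their title. No 2 libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom over all pairs within a group was 47.2.

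Counts per OTU were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMMwsp scaling factors and robust dispersion and quasi-likelihood fits, in 1 model of all 59 libraries. OTUs with at least 10 reads in at least 5 libraries were tested, which left 648 OTUs holding 85.8% to 99.6% of the reads of a library. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and OTUs with an adjusted p under 0.05 are called changed. There were 7 comparisons: 6 between pairs of groups, and the difference between the AOS effect under HFD and the AOS effect without it. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. The TMMwsp factors differed between groups, with geometric means of 1.61 in control, 2.19 in AOS, 0.995 in HFD, 0.716 in HFD+AOS, 0.626 in HFD+AOS-FMT and 0.605 in HFD+control-FMT. The scaling therefore moved all fold changes of a comparison: the median log2 fold change over tested OTUs was 0.61 for HFD versus control with TMMwsp and 0.00 with library totals alone, -0.17 and -0.46 for HFD+AOS versus HFD, -0.60 and -0.87 for HFD+AOS-FMT versus HFD, -0.19 and -0.83 for HFD+control-FMT versus HFD, 0.00 and 0.24 for AOS versus control, and -0.38 and -0.92 for the difference between the AOS effects.

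Relative abundance is the percent of a library's reads. The reads held by changed OTUs are given for the same libraries that called them, so that choice sets part of the gap between groups. Folds between groups are ratios of pooled shares, a pooled share being a group's reads of the OTU over all reads of that group. Where a group had no read of an OTU, the fold is a lower bound against 3 reads over all reads of that group. Where it had reads, the fold carries a 95% interval for counting error. These intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The OTUs named in each comparison were chosen by a rule fixed before the data were examined: up to 2 higher and 2 lower OTUs with an adjusted p under 0.05 and a mean of at least 0.1% of reads in at least 1 of the compared groups, in order of absolute log2 fold change.

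Bray-Curtis dissimilarity of relative abundances was tested with adonis2 of vegan 2.7.1 by label permutations, whose number allows a permutation p of 1e-05 at the least, and its spread with betadisper, and displayed by principal coordinates. Shannon diversity and the number of observed OTUs were averaged over 10 random draws of 32134 reads per library, the depth of the smallest library. The distance to control is a library's mean Bray-Curtis dissimilarity to the control libraries. Group means were compared by two-sided permutation tests with scipy 1.17.1, exact where a group had fewer than 10 libraries and with 100000 resamples otherwise, adjusted over the 6 comparisons, or the 4 of the distance to control. The AOS effects on diversity with and without HFD were compared by permuting the AOS labels within each diet. Opposite fold changes of OTUs in HFD versus control and in a second comparison against HFD were counted with the HFD libraries divided at random into 2 sets of 5, 1 for each comparison, in 100 divisions.

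The count test was tested on simulated data drawn from the means and totals of these libraries, with 200 of the 648 OTUs changed. For HFD versus control it recovered 7.46% of OTUs changed by 4-fold, 49.3% of those changed by 16-fold and 87.9% of those changed by 64-fold, and 2.04% of its calls were false. For HFD+AOS-FMT versus HFD+control-FMT the shares were 10.4%, 38.8% and 92.4%, and 7.84% of the calls were false. The simulated libraries of a group were drawn independently, so these false shares hold for groups without inner structure. Random regroupings of the real libraries of the 2 transfer groups gave a median of 36 calls, against 34 for the groups as given. The simulated share of 7.84% is therefore not the false share of the real calls between these groups. At this spread between mice the count test thus detects large changes in single OTUs and misses most 4-fold ones.

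The alternatives planned before the data were examined were DESeq2 1.42.0 with poscounts size factors, library totals alone, no filter beyond a read in at least 2 libraries, a filter of 10 reads in at least 20 libraries, the title number as a block, each library left out in turn, square roots or Jaccard presence in place of Bray-Curtis, diversity without thinning or without OTUs seen in fewer than 5 libraries, and all tested in place of changed OTUs in the count of opposite fold changes. Alternatives chosen after seeing the data were limma 3.58.1 on centred log-ratios of OTU counts with 0.5 added, the fits without HFD+AOS 11 and 12 and HFD+control-FMT 6, the fits with title numbers up to 10 only, diversity without thinning and with the log2 library total as a covariate for the difference between the AOS effects, and each library left out in turn in the count of OTUs lower in HFD and called higher again.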

Results

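Bacterial 16S rDNA was counted in the colon of 59 ICR mice, an outbred strain, after the colon contents had been removed. The series asked whether a transfer of microbiota named for AOS changes the colon under a high fat diet (HFD). Its 6 groups were control, AOS at 10 mg/kg, HFD, HFD+AOS, HFD+AOS-FMT with 9 mice, and HFD+control-FMT, each of the other groups with 10 mice. Library totals were 42454 to 52665 reads in control, 32134 to 49571 in AOS, 43618 to 52941 in HFD, 45980 to 50280 in HFD+AOS, 38288 to 56324 in HFD+AOS-FMT and 47617 to 63470 in HFD+control-FMT.

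The first principal coordinate, which held 30.8% of the variance, set part of the HFD libraries apart from control. All 20 control and AOS libraries lay below 0 on it. All 13 HFD and HFD+AOS libraries with title numbers up to 10 lay above 0, and the 7 with numbers above 10, which were HFD 11, 17, 18, 19 and 20 and HFD+AOS 11 and 12, lay below it. In the transfer groups, HFD+control-FMT 6 lay at -0.208 and the other 18 libraries above 0. The HFD group thus held 5 libraries on each side, and this division enters every comparison with HFD given here.

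**Figure D1:**
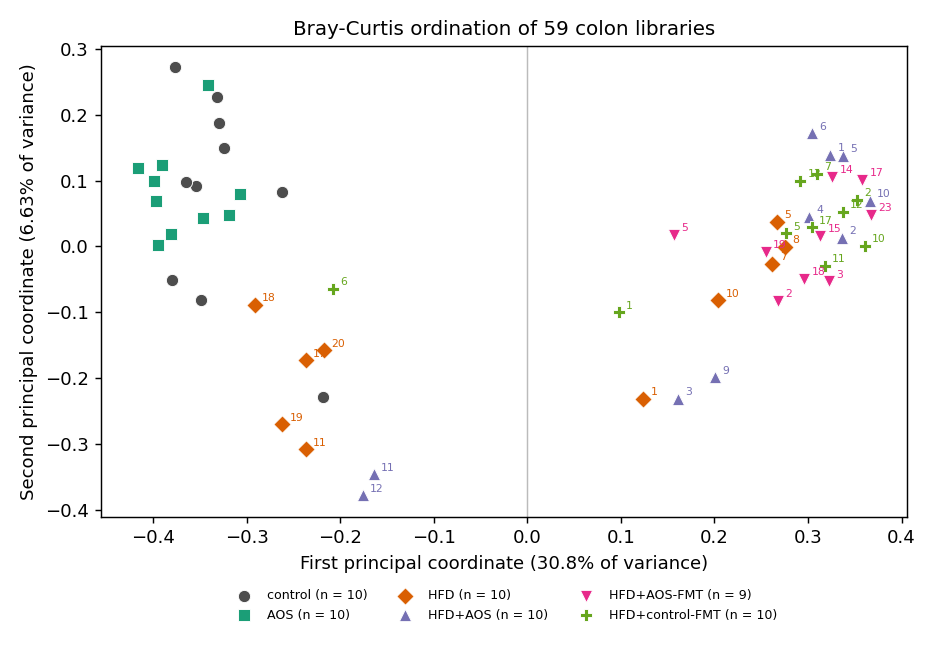
Each point is 1 colon library placed by its Bray-Curtis dissimilarity to the others, with the first principal coordinate (30.8% of variance) on the horizontal and the second (6.63%) on the vertical axis; colours and shapes give the 6 groups and small digits the title numbers in the HFD groups. All 20 control and AOS libraries lie left of 0, together with 5 HFD, 2 HFD+AOS and 1 HFD+control-FMT library.

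HFD and control mice differed in OTUs that held a large part of the reads. OTU1553 rose from 0.00115% ± 0.00228 (SD, n = 10) of reads in control to 6.58% ± 9.54 (SD, n = 10) in HFD, a 6130-fold difference in pooled shares (95% counting interval 2630 to 18900). It was detected in 9 of 10 HFD and 3 of 10 control libraries, but at unlike levels within HFD. The HFD libraries numbered up to 10 held 2.32% to 24.4% of OTU1553, and those numbered above 10 at most 0.382%. OTU1627 had 12383 reads in all 10 HFD libraries, at 2.51% ± 3.64 (SD, n = 10), and no read in control, at least 4070-fold higher. OTU123 went the other way, with 0.737% ± 1.03 (SD, n = 10) and a read in all 10 control libraries against no read in HFD, at least 1170-fold lower. OTU86 was at 0.817% ± 1.74 (SD, n = 10) in control, from 3 of 10 libraries, and had no read in HFD, at least 1280-fold lower; control 4 held 60.1% of its control reads.

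Of the 648 tested OTUs, 181 rose and 149 fell with HFD. The OTUs that rose held 51.6% ± 24.5 (SD, n = 10) of HFD reads and 3.93% ± 1.87 (SD, n = 10) of control reads, and those that fell held 0.891% ± 0.566 of HFD and 38.8% ± 16.1 of control reads. Of the risen OTUs 64 had no read in control, and of the fallen OTUs 57 had none in HFD. The log2 fold change was 13.31 ± 1.92 (SE; adjusted p = 1.6e-06) for OTU1553, 13.39 ± 2.37 (adjusted p = 2.54e-05) for OTU1627, -11.82 ± 1.78 (adjusted p = 9.98e-06) for OTU123 and -12.09 ± 2.91 (adjusted p = 0.000842) for OTU86. That of OTU86 was -9.60 without control 4 (adjusted p = 0.00247), and limma on centred log-ratios did not call it (-2.20, adjusted p = 0.152). Diet explained 15.2% of the Bray-Curtis variance (adonis2 permutation test, adjusted p = 0.00018), with no difference in spread past the threshold (p = 0.74). With title numbers up to 10 only, diet explained 30% (adonis2 permutation test, adjusted p = 0.00516). There the spread differed too (0.35 in HFD and 0.515 in control, permutation p = 0.00175), so a shift of the centre is not separated from a narrower spread. Observed OTUs fell from 519 ± 96.3 to 413 ± 31.2 (SD, n = 10 each; permutation test, adjusted p = 0.0178). Shannon diversity was 3.87 ± 0.338 in HFD and 4.11 ± 0.456 in control (SD, n = 10 each; adjusted p = 0.248), which the spread between libraries did not separate. With title numbers up to 10 only, observed OTUs were 414 ± 13.9 (SD, n = 5) and 514 ± 107 (SD, n = 8) and no longer passed the exact permutation test (adjusted p = 0.152). A filter of 10 reads in at least 20 libraries left 69 changed OTUs among 206 tested, and no filter beyond a read in 2 libraries gave 582. Which direction held more OTUs depended on the setting: 141 rose and 164 fell with library totals alone, 277 and 305 without the filter, 123 and 135 with limma, and 141 and 129 with DESeq2.

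AOS without HFD went with higher Shannon diversity, and few single OTUs passed the test. Shannon diversity rose from 4.11 ± 0.456 to 4.58 ± 0.0952 (SD, n = 10 each; permutation test, adjusted p = 0.00204). Control 4 lay at 3.018, apart from the other control libraries at 4.23 ± 0.264 (SD), and this comparison was not run without it. The most abundant OTU of a library took 8.07% ± 1.91 (SD, n = 10) of reads in AOS and 16.7% ± 6.95 (SD, n = 10) in control. OTU152 rose from 0.000814% ± 0.00257, from 4 reads in 1 of 10 control libraries, to 0.455% ± 0.689 in 7 of 10 AOS libraries (SD, n = 10 each). This was a 540-fold difference in pooled shares (95% counting interval 211 to 1990), with a log2 fold change of 7.22 ± 1.52 (SE; adjusted p = 0.00601). OTU1627 was also higher in AOS, at 0.544% ± 1.72 (SD, n = 10) and at least 978-fold over control (adjusted p = 0.00601), but AOS 4 held 99.9% of its reads and the change was lost without that library (log2 fold change 1.30, adjusted p = 0.551).

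In all, 5 OTUs rose and 2 fell with AOS, and 86 had an unadjusted p under 0.05. Observed OTUs numbered 561 ± 44.1 in AOS and 519 ± 96.3 in control (SD, n = 10 each; permutation test, adjusted p = 0.267), and AOS explained 6.78% of the Bray-Curtis variance (adonis2 permutation test, adjusted p = 0.137), neither past the threshold. The count of changed OTUs was small under each alternative but one, from 1 with the filter of 20 libraries to 14 with DESeq2 (5 higher, 9 lower) and 87 without a filter, and limma on centred log-ratios gave 13 (6 higher, 7 lower). Leaving out 1 library gave 2 without AOS 4, 12 without AOS 8 or AOS 10, 4 without AOS 6, AOS 9, control 1 or control 12, and 3 without control 4, 5, 7, 8 or 10.

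**Figure D2:**
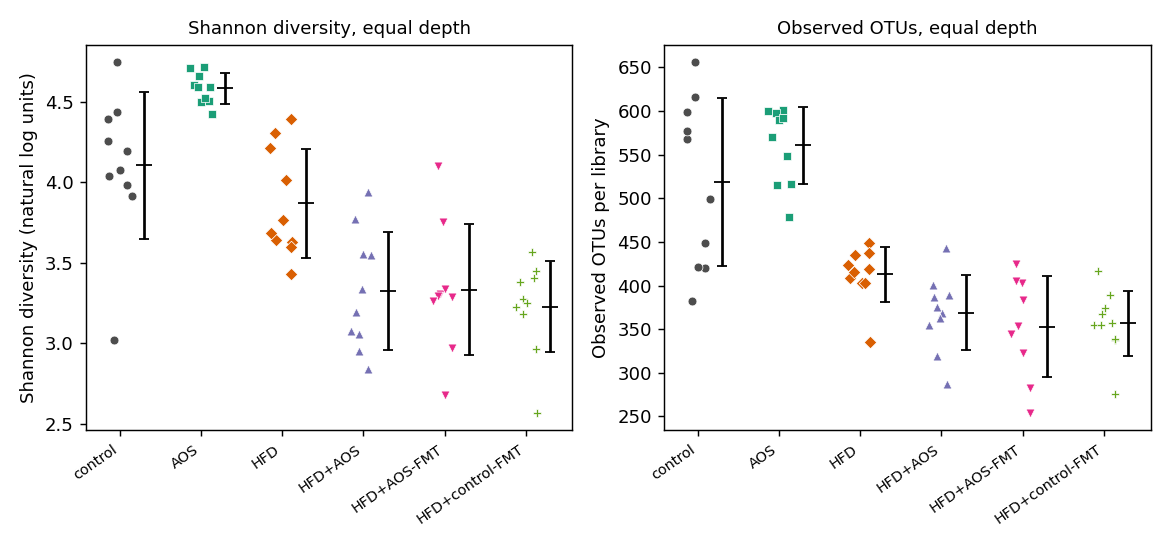
Shannon diversity (left, natural log units) and observed OTUs (right) of each library at 32134 reads, by group; each point is 1 library and the bars give the mean and SD. AOS libraries lie between 4.427 and 4.715 on the Shannon axis, and the means of the 3 treated HFD groups, 3.33, 3.33 and 3.23, lie below the HFD mean of 3.87.

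Under HFD, mice given AOS had lower diversity, and more OTUs fell than rose. Shannon diversity fell from 3.87 ± 0.338 in HFD to 3.33 ± 0.367 in HFD+AOS (SD, n = 10 each; permutation test, adjusted p = 0.00788), and observed OTUs from 413 ± 31.2 to 369 ± 42.9 (adjusted p = 0.0239). OTU107 was found in 6 of 10 HFD+AOS libraries at a mean of 1.07% ± 1.23 (SD, n = 10) and had no read in HFD, control, AOS or HFD+control-FMT, at least 1710-fold over HFD, with a log2 fold change of 12.71 ± 2.71 (SE; adjusted p = 0.00711). OTU212 and OTU615 were lower, with no read in HFD+AOS against 987 and 816 reads in HFD (adjusted p = 0.0114 and 0.00917). HFD 20 held 98.5% of the HFD reads of OTU212, HFD 18 held 100% of those of OTU615, and both calls were lost without the library concerned (adjusted p = 0.218 and 1).

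Of 648 OTUs, 9 rose and 60 fell with AOS under HFD. The fallen OTUs held 8.68% ± 9.20 (SD, n = 10) of HFD reads and 0.131% ± 0.108 (SD, n = 10) of HFD+AOS reads. AOS explained 8.95% of the Bray-Curtis variance under HFD, short of the threshold (adonis2 permutation test, adjusted p = 0.112). The number of changed OTUs was 39 without HFD 18, and limma on centred log-ratios called 8 OTUs, 6 higher and 2 lower. With title numbers up to 10, edgeR called 0 OTUs, with 45 at an unadjusted p under 0.05, while the lower Shannon diversity held (3.19 ± 0.266, n = 8, against 3.71 ± 0.212, n = 5, SD; exact permutation test, adjusted p = 0.0124). In a fit without HFD+AOS 11 and 12 and HFD+control-FMT 6, which were chosen by where they lay, 132 OTUs changed between HFD+AOS and HFD, and AOS explained 15.9% of the variance (adonis2 permutation test, adjusted p = 0.0117); the spread differed too (0.344 and 0.507, permutation p = 0.00099), so a shift of the centre is not separated from a narrower spread. Without HFD+AOS 11 or HFD+AOS 12 alone, 80 and 78 changed.

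The effect of AOS on diversity differed between the diets. Shannon diversity was 0.4774 higher with AOS than without it in mice off HFD and -0.5421 under HFD, a difference of -1.02 ± 0.216 (SE; n = 10 in each of 4 groups; permutation test, adjusted p = 2e-05 over 2 measures, from the smallest p that the resamples can give, 1e-05). For observed OTUs the difference was -86.3 ± 37.5 (adjusted p = 0.0251), and with the library total as a covariate, without thinning, it was -51.4 ± 38.2 (SE), within 2 SE of 0. At OTU level, the AOS effect was more positive under HFD for 6 OTUs and more negative for 45. Of these, 5 and 21 had a mean of at least 0.1% of reads in a compared group. Among them, OTU86 and OTU20 had the largest positive differences, 10.66 ± 3.12 (SE; adjusted p = 0.0293) and 8.28 ± 2.08 (adjusted p = 0.0104) on the log2 scale, and OTU615 and OTU721 the largest negative ones, -13.50 ± 2.91 (adjusted p = 0.00633) and -13.00 ± 2.69 (adjusted p = 0.00608). Each of these 4 calls was lost with a single library left out. Without HFD 18 the differences of OTU615 and OTU721 fell to -3.96 and -3.10 (adjusted p = 1 for both), and without HFD+AOS 11 that of OTU20 fell to 3.05 (adjusted p = 0.298). That of OTU86 was 8.17 without control 4 and 5.71 without HFD+AOS 4 (adjusted p = 0.0689 and 0.274), and stayed at 10.66 without HFD 18, where only the adjusted p moved, to 0.0585. The count of 51 OTUs was 14 without HFD 18 and 30 without AOS 4, and limma on centred log-ratios called 0, with 83 at an unadjusted p under 0.05, where DESeq2 called 42.

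Mice that received the transfer named for AOS had a less rich community than mice on HFD alone. OTU15 and OTU113 fell from 0.849% ± 2.65 and 0.757% ± 1.75 in HFD (SD, n = 10) to no read in the 9 HFD+AOS-FMT libraries, at least 1400-fold and 1130-fold lower, with log2 fold changes of -11.98 ± 2.64 (SE; adjusted p = 0.00151) and -11.48 ± 2.36 (adjusted p = 0.000932). OTU107 and OTU148 rose, to 0.625% ± 1.76 in 5 of 9 and 0.234% ± 0.61 in 6 of 9 libraries (SD, n = 9), at least 1010-fold and 385-fold over HFD, which had no read of either (adjusted p = 0.00228 and 0.00129). Most reads of these OTUs came from 1 library each, with 98.8% of the HFD reads of OTU15 in HFD 18 and 95.7% of the reads of OTU107 in HFD+AOS-FMT 14. Without HFD 18 the log2 fold change of OTU15 was -5.44 (adjusted p = 0.0274), without HFD+AOS-FMT 14 that of OTU107 went from 11.97 to 7.50 (adjusted p = 0.00969), and without HFD+AOS-FMT 17 that of OTU148 from 11.18 to 7.46 (adjusted p = 0.008). Limma on centred log-ratios did not call OTU15 (-1.70, adjusted p = 0.428). The HFD libraries numbered up to 10 had no read of OTU15 and at most 0.00893% of OTU113. With title numbers up to 10 only, the log2 fold change was 0 for OTU15 and -4.02 for OTU113 (edgeR, adjusted p = 0.876). Both falls thus rest on the HFD libraries numbered above 10. Shannon diversity fell to 3.33 ± 0.409 (SD, n = 9; exact permutation test, adjusted p = 0.0106) and observed OTUs to 353 ± 58.0 (SD, n = 9; exact permutation test, adjusted p = 0.0213).

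In HFD+AOS-FMT against HFD, 20 OTUs rose and 142 fell. The fallen OTUs held 27.6% ± 27.4 (SD, n = 10) of HFD and 0.176% ± 0.0976 (SD, n = 9) of HFD+AOS-FMT reads, and 90 of them had no read after the transfer. The HFD share was uneven between libraries, so it is not the size of a loss common to all HFD mice. The groups explained 17.1% of the Bray-Curtis variance (adonis2 permutation test, adjusted p = 0.00501), and their spread differed too (mean distance to the group centre 0.333 and 0.507, p = 2e-05), so a shift of the centre is not separated from a narrower spread. With title numbers up to 10 (n = 3 and 5), edgeR called 0 OTUs, with 30 at an unadjusted p under 0.05, and community variance, Shannon diversity and observed OTUs lay short of the threshold in permutation tests (adjusted p = 0.643, 0.75 and 0.429). With so few libraries a permutation p falls to about 0.0179 at the least. Beside the other comparisons, that is too high for the adonis2 test to pass after adjustment. Limma on centred log-ratios called 59 OTUs and turned the balance, with 38 higher and 21 lower.

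The transfer named for control mice gave a similar count of changes against HFD. OTU109 appeared in 7 of 10 HFD+control-FMT libraries at 0.615% ± 0.591 (SD, n = 10) and had no read in HFD, control, AOS or HFD+AOS-FMT, at least 945-fold over HFD, with a log2 fold change of 11.96 ± 1.83 (SE; adjusted p = 0.000222). OTU13 rose from 0.0663% ± 0.0883 to 2.32% ± 7.12 (SD, n = 10 each), 35.1-fold (95% counting interval 31.3 to 39.4; adjusted p = 0.0115), but HFD+control-FMT 1 held 97.3% of its reads and the call was lost without it (log2 fold change 0.51, adjusted p = 0.895). OTU15 and OTU1381 fell from 0.849% ± 2.65 and 0.702% ± 1.74 in HFD (SD, n = 10 each) to no read and to 1 read (adjusted p = 0.00135 and 0.00234). HFD 18 held 98.8% of the HFD reads of OTU15, and without it the log2 fold change went from -11.98 to -5.44 (adjusted p = 0.0209). HFD 17 held 79.6% of those of OTU1381, with -10.29 and, without it, -8.17 (adjusted p = 0.00645). Limma on centred log-ratios called neither (adjusted p = 0.432 and 0.0775). The HFD libraries numbered up to 10 had no read of OTU15 or OTU1381. Shannon diversity fell to 3.23 ± 0.284 (SD, n = 10; permutation test, adjusted p = 0.0006) and observed OTUs to 357 ± 37.1 (SD, n = 10; adjusted p = 0.013).

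Against HFD, 43 OTUs rose and 117 fell in HFD+control-FMT, and the groups explained 12.4% of the Bray-Curtis variance (adonis2 permutation test, adjusted p = 0.0246; spread p = 0.0685). The fallen OTUs held 25.3% ± 26.1 of HFD and 0.253% ± 0.116 of HFD+control-FMT reads (SD, n = 10 each). With title numbers up to 10 (n = 6 and 5), edgeR called 2 OTUs, with 89 at an unadjusted p under 0.05, and the community test lost its call (adonis2 permutation test, adjusted p = 0.654), whereas Shannon diversity and observed OTUs stayed lower (exact permutation tests, adjusted p = 0.0124 and 0.013). Without HFD+control-FMT 6, 18 OTUs rose and 126 fell. The groups then explained 16.2% of the variance (adonis2 permutation test, adjusted p = 0.0054), and their spread differed (0.325 and 0.507, permutation p = 0.00062). A shift of the centre is thus not separated from a narrower spread here either. Limma on centred log-ratios called 27 OTUs, 18 higher and 9 lower.

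The 2 transfer groups were not separated as communities. They explained 5.25% of the Bray-Curtis variance (adonis2 permutation test, adjusted p = 0.515), and Shannon diversity was 3.33 ± 0.409 (n = 9) in HFD+AOS-FMT and 3.23 ± 0.284 (n = 10) in HFD+control-FMT (SD; exact permutation test, adjusted p = 0.522), a difference of 0.1065 ± 0.16 (SE). The count test called single OTUs. OTU109 had no read in HFD+AOS-FMT, at least 885-fold lower than in HFD+control-FMT (log2 fold change -11.96 ± 1.98, SE; adjusted p = 0.000916). OTU107 was the reverse, with no read in HFD+control-FMT and at least 1090-fold higher in HFD+AOS-FMT (log2 fold change 11.97, adjusted p = 0.0104), but HFD+AOS-FMT 14 held 95.7% of its reads. Its log2 fold change was 7.50 without that library (adjusted p = 0.0342), and limma on centred log-ratios and the fit with title numbers up to 10 did not call it (adjusted p = 0.859 and 0.275). OTU1480 was at least 6940-fold lower in HFD+AOS-FMT (adjusted p = 0.00116), but HFD+control-FMT 6 held 99.7% of its reads, at 37.7% of that library, and the call was lost without it (adjusted p = 0.07). In all, 5 OTUs were higher and 29 lower in HFD+AOS-FMT, and without HFD+control-FMT 6 the count was 5, with 4 higher and 1 lower. Limma on centred log-ratios called 1 OTU, which was lower, and DESeq2 called 62.

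None of the 3 treated HFD groups lay nearer to control than HFD alone. The mean Bray-Curtis dissimilarity to the control libraries was 0.849 ± 0.0412 (SD, n = 10) in HFD, 0.893 ± 0.033 (SD, n = 10) in HFD+AOS, 0.900 ± 0.0227 (SD, n = 9) in HFD+AOS-FMT and 0.898 ± 0.024 (SD, n = 10) in HFD+control-FMT, and control libraries lay 0.771 ± 0.0429 (SD, n = 10) from each other. Each treated group was farther from control than HFD (permutation tests, exact for HFD+AOS-FMT; adjusted p = 0.024, 0.00928 and 0.00928), and the 2 transfer groups were not separated (exact permutation test, adjusted p = 0.851). With title numbers up to 10, HFD lay at 0.883 ± 0.00818 (SD, n = 5), and none of these differences passed the threshold (exact permutation tests, adjusted p = 0.174, 0.667 and 0.364). The treated groups then had 8, 3 and 6 libraries. For HFD+AOS-FMT the smallest p of the exact permutation test was 0.0179. Adjusted beside the other comparisons, it could not have passed, so that result decides nothing.

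**Figure D3:**
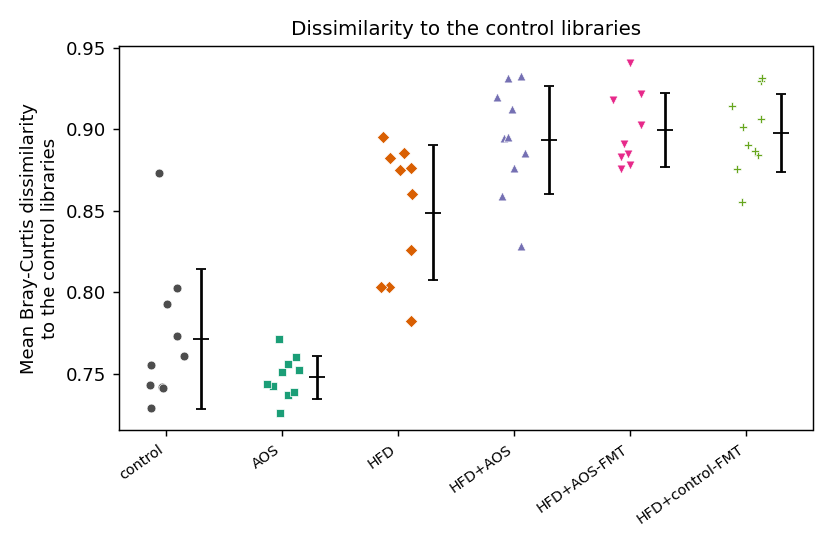
Mean Bray-Curtis dissimilarity of each library to the control libraries (vertical axis, no unit, not starting at 0), by group; each point is 1 library, a control library is set against the other control libraries, and the bars give the mean and SD. HFD libraries spread from 0.7825 to 0.8955, and the means of the 3 treated HFD groups lie at 0.893, 0.900 and 0.898.

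Few of the OTUs that were lower under HFD were called higher again in the treated groups. Of the 149 OTUs lower in HFD than in control, 4 were called higher again in HFD+AOS, 5 in HFD+AOS-FMT and 23 in HFD+control-FMT, each against HFD, while 5, 11 and 4 fell further. Among all 648 tested OTUs, 9, 20 and 43 rose in these comparisons, so few OTUs of any kind were called higher. Of the 149, 57 had no read in HFD and so no room to fall further. An OTU not called may still have risen, since the count test misses most 4-fold changes. The 23 came to 1 without HFD+control-FMT 6, which lies on the control side of the ordination, the 4 to 2 without HFD+AOS 11 and the 5 to 3 without HFD+AOS-FMT 5. Of the 181 OTUs higher in HFD, 9, 23 and 23 were called lower. OTU123 had no read in HFD+AOS or HFD+AOS-FMT and 9 reads in 1 of 10 HFD+control-FMT libraries. With separate HFD libraries in the 2 comparisons, the median share of diet-changed OTUs whose fold change pointed back toward control was 37.0% in HFD+AOS (range over divisions 22.3% to 50.4%), 28.0% in HFD+AOS-FMT (15.9% to 44.6%) and 41.5% in HFD+control-FMT (27.2% to 60.1%). With all HFD libraries in both comparisons the shares were 44.4%, 32.4% and 46.1%. The 2 sets of a division are tied, since HFD libraries on the control side placed in 1 set are missing from the other. No level without an effect was computed, so these shares do not tell a move toward control from one away from it. Between the transfer groups, in a comparison without HFD libraries, 37.7% of 265 diet-changed OTUs pointed toward control in HFD+AOS-FMT against HFD+control-FMT, where permuted labels gave a median of 47.7% (p = 0.703).

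The lists of OTUs changed after the 2 transfers overlapped, but both rest on the same HFD libraries. Of 142 and 117 OTUs lower than in HFD after the AOS and the control transfer, 101 were in both lists, against 25.6 for independent lists. Groups simulated without any effect against the same HFD libraries shared a median of 0, which is chance with no effect and not the level that shared libraries bring to lists of this length. Of 20 and 43 higher OTUs, 11 were in both, against 1.33 for independent lists. With the HFD libraries divided between the comparisons, the shared OTUs numbered a median of 42 lower (17 to 53) and 1 higher (0 to 4) in fits with 5 HFD libraries each; part of the overlap of the full lists may come from the shared HFD libraries.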

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

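All tests of explanations and all counts of other splits in this part were chosen after the results were seen, and the tests for mislabelling and for OTUs gained with the transfers replaced earlier versions whose outcomes were already known.

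Under HFD, the libraries with title numbers above 10 looked more like control than those with numbers up to 10. All 7 such libraries of HFD and HFD+AOS lay below 0 on the first principal coordinate. Mislabelled control or AOS mice of the series are argued against: of 94 OTUs found in every control and AOS library, all 7 libraries detected fewer at 32134 reads, 82.5% to 89.2% (HFD 19), than control and AOS libraries left out of that definition, 96.9% ± 2.47 (SD, n = 20) and 92.6% at the lowest. Of 19 OTUs found in at least 80% of the transfer-group libraries and without a read in control or AOS, 5 of the 7 libraries detected more than the 3 of the highest left-out control or AOS library, and HFD 19 and HFD 20 detected 2 each, so that these 2 libraries are told from control and AOS by the first set alone. A batch shared by high numbers in every group is argued against, since 0 of the 10 transfer-group libraries numbered above 10 lay below 0, and so is depth, since 6 of the 7 totals lay within the range of the 13 others; samples from outside the series and a second cohort of HFD mice stay open and untested, and no biological explanation was tested.

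Shannon diversity moved in opposite directions with AOS in the 2 diets, a difference between the AOS effects of -1.02, and observed OTUs differed likewise by -86.3. Single libraries are argued against as the cause, since the permutation p was at most 0.0002 with any 1 of the 40 libraries left out and the difference stayed between -1.09 and -0.899. Libraries with title numbers above 10 are argued against too, with a difference of -0.986 ± 0.226 (SE; n = 8, 10, 5 and 8; permutation p = 5e-05) among numbers up to 10, and so is depth as the whole cause for Shannon diversity, since the difference with the log2 library total as a covariate was -0.864 ± 0.219 (SE). For observed OTUs the difference was -86.3 ± 37.5 (SE) with all libraries thinned to equal depth and -78.9 ± 37.7 (SE) without thinning. Equal depth did not shrink it, which argues against depth in the sense that more reads find more OTUs. The slope in the covariate model, -184 ± 86.5 (SE) OTUs per doubling of the total, had the opposite sign to such an effect. With that covariate the difference was -51.4 ± 38.2 (SE), so a part that goes with the library total for another reason stays open. A response to AOS that depends on the diet is a hypothesis in line with these values; cages shared within a group were not tested and stay open.

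Transfer-group libraries held fewer OTUs typical of the group their transfer was named for than HFD libraries did. Of 297 OTUs detected in at least 80% of control libraries with all reads counted, 150 ± 16.3 (SD, n = 10) were detected in HFD+control-FMT and 181 ± 21.1 (SD, n = 10) in HFD at 32134 reads, a difference of -30.6 (permutation p = 0.00258), and of 337 such AOS OTUs 144 ± 24.1 (SD, n = 9) in HFD+AOS-FMT and 194 ± 27.0 (SD, n = 10) in HFD, a difference of -50.6 (exact permutation p = 0.000173). A gain of such OTUs with the transfer is not seen, but among title numbers up to 10 the differences were -16 and -27.5 (exact permutation p = 0.0563 and 0.107), so the control-like HFD libraries may set part of them and the question stays open. Observed OTUs of all kinds were fewer too, with differences from HFD of -56.07 in HFD+control-FMT and -60.09 in HFD+AOS-FMT, so the loss is not shown to be one of donor-type OTUs in particular. The donors were not analysed here, and the biological explanation, loss of donor OTUs under HFD, was not tested.

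A library lay far from the rest of its group in 11 of 59 tested sets of values, where chance gives about 1 in 20 for values without ties; many of the sets are shares of OTUs named for large changes, which often rest on 1 library, so that level does not hold for them. Control 4 had a Shannon diversity of 3.018, where the other control libraries had 4.23 ± 0.264 (SD, n = 9), and a mean dissimilarity to the other control libraries of 0.8731, where they had 0.760 ± 0.0251. HFD 18 had 335.5 observed OTUs, where the other HFD libraries had 421 ± 16.2 (SD, n = 9). HFD+control-FMT 6 lay at -0.208 on the first principal coordinate, where its group lay at 0.294 ± 0.0785 (SD, n = 9). On the log scale, AOS 4 stood apart with 5.43% OTU1627, HFD 20 with 2.06% OTU212, HFD 18 with 1.54% OTU615 and 8.38% OTU15, and HFD+control-FMT 6 with 37.7% OTU1480. In 2 further sets all other libraries were at 0 and the distance was fixed by those zeros, with 4 reads or 0.00814% of OTU152 in control 4 and 1 read or 0.00158% of OTU1381 in HFD+control-FMT 6, which says nothing beyond counting noise; the other libraries were at 0 for OTU615 too.

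EdgeR called the difference between the AOS effects for 51 OTUs, a count for which chance is not excluded and where limma called 0 (83 at an unadjusted p under 0.05) and DESeq2 42. The named differences on the log2 scale were 10.66 for OTU86, 8.28 for OTU20, -13.50 for OTU615 and -13.00 for OTU721, and each of these calls was lost with a single library left out.

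Other splits of the compared libraries into groups of the same sizes were fitted to see how often they gave as many changed OTUs. For HFD versus control, 1 of 100 splits, the real one, gave 330, with 161 the highest other. For HFD+AOS-FMT versus HFD, 1 of 100 gave 162, with 136 the highest other. No other split reached these counts, which argues against chance for libraries that can be exchanged, a condition that shared cages would break. For HFD+control-FMT versus HFD, 4 of 100 gave 160 or more, the highest other 185, so 3 other splits gave as many. Chance is not excluded there, since 7 comparisons were tried without adjustment and 4 in 100 lies close to 5 in 100. Chance is not excluded for HFD+AOS versus HFD, with 7 of 100 splits at 69 or more and 109 the highest, for the difference between the AOS effects, with 10 of 100 at 51 or more and 72 the highest, for AOS versus control, with 50 of 100 at 7 or more and 31 the highest, or for HFD+AOS-FMT versus HFD+control-FMT, with 65 of 100 at 34 or more and 53 the highest.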

How the results depend on the processing

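Fits with limma, without HFD+AOS 11 and 12 and HFD+control-FMT 6 or with title numbers up to 10, all alternatives for the difference between the AOS effects on diversity, and all for OTUs called higher again, were chosen after seeing the data. Diversity and distance to control kept their side of the threshold in 52 recomputed values, some uncalled ones changing sign. The call was lost in 7. Of these 1 was the difference between the AOS effects on observed OTUs with the library total as a covariate (-51.4 ± 38.2, SE). The adonis2 permutation test gave counts of 18 and 2, with 1 call gained. Counts of changed OTUs stayed within 1.5 times of their value in 20 fits with another setting and 142 with 1 library left out, and moved further in 33 and 16. The fold changes of named OTUs kept direction and call in 106 and 542, lost the call in 47 and 10, and changed sign or went to 0 in 6 and 1. Diversity without thinning kept every call, although thinning changed Shannon diversity by at most 0.00792 in the 4 groups without transfer; the depth of 32134 to 63470 reads was not varied for OTU calls. The alternatives at genus level, for taxon lists and without reagent or diet OTUs were not run, as the files do not pair OTU IDs with taxa.

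No filter beyond a read in 2 libraries gave 582 changed OTUs for HFD versus control, 87 for AOS versus control, 251 for HFD+control-FMT versus HFD and 71 between the transfer groups, among 1349 tested. A filter of 10 reads in 20 libraries gave, among 206 tested, 69, 1, 11, 52, 44, 6 and 11 for HFD versus control, AOS versus control, HFD+AOS, HFD+AOS-FMT and HFD+control-FMT each versus HFD, between the transfer groups and for the difference between the AOS effects; fewer OTUs were tested. DESeq2 gave 14 for AOS versus control and 62 between the transfer groups. Limma gave 13 for AOS versus control, 8, 59 and 27 for HFD+AOS, HFD+AOS-FMT and HFD+control-FMT versus HFD, 1 between the transfer groups and 0 for the difference between the AOS effects. The causes of these differences between tools were not tested.

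Without HFD+AOS 11 and 12 and HFD+control-FMT 6, which were picked by their place in the ordination, 132 OTUs changed in HFD+AOS versus HFD, 5 between the transfer groups and 99 in the difference between the AOS effects, and HFD+AOS explained 15.9% of the variance. With title numbers up to 10, which leaves fewer libraries, edgeR called 0 OTUs in HFD+AOS versus HFD, HFD+AOS-FMT versus HFD, between the transfer groups and for the difference between the AOS effects (45, 30, 66 and 56 at an unadjusted p under 0.05) and 2 in HFD+control-FMT versus HFD. There adonis2 gave 14.5% for HFD+AOS-FMT and 9.42% for HFD+control-FMT versus HFD, Shannon diversity differed by -0.09825 and observed OTUs by -53.23 for HFD+AOS-FMT versus HFD, observed OTUs differed by -100.2 for HFD versus control, and distances to control by 0.02298, 0.01124 and 0.01987 for HFD+AOS, HFD+AOS-FMT and HFD+control-FMT versus HFD, all short of the threshold. For HFD+AOS-FMT versus HFD (n = 3 and 5), the adonis2 and distance tests were too small to pass after adjustment. The log2 fold change of OTU615 in HFD+AOS versus HFD, up to -9.7 (without HFD 7) in other fits with 1 library left out, was 0 there, 0.03 with the replicate block, 0.4 with DESeq2 and 0 without HFD 18; that of OTU15 was 0 versus HFD in both transfer groups and that of OTU1381 in HFD+control-FMT versus HFD 1.68 with title numbers up to 10, which leave out HFD 17 and HFD 18.

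The title numbers did not pair the libraries throughout: same-number correlations were above 0.1 for 1 of 6 numbers in HFD versus control, 0 of 8 in AOS versus control, 3 of 4 in HFD+AOS versus HFD, 1 of 4 and 2 of 6 in HFD+AOS-FMT and HFD+control-FMT versus HFD and 1 of 3 between the transfer groups, and not every library correlated best with its own number. In HFD+AOS versus HFD the median same-number correlation was 0.357, against -0.0338 for other numbers, but only 1 of 4 numbers correlated best with itself. The shared numbers there joined libraries on the same side of 0 on the first principal coordinate. Other numbers joined libraries of both sides too, so the correlation does not tell a pairing by number from that division. With the number as a block, edgeR called 294 OTUs in HFD versus control, 1 in AOS versus control, 0, 4 and 2 for HFD+AOS, HFD+AOS-FMT and HFD+control-FMT versus HFD, 2 between the transfer groups and 0 for the difference between the AOS effects; the zeros had 64 and 46 OTUs at an unadjusted p under 0.05. With 1 library left out, the counts ranged from 298 to 340 for HFD versus control, 2 to 12 for AOS versus control, 39 (without HFD 18) to 80 for HFD+AOS versus HFD, 132 to 177 and 129 to 170 for HFD+AOS-FMT and HFD+control-FMT versus HFD, 5 (without HFD+control-FMT 6) to 44 between the transfer groups, and 14 (without HFD 18) to 67 for the difference between the AOS effects. Of the OTUs lower in HFD than in control, those called higher again came to 1 in HFD+control-FMT without HFD+control-FMT 6, to 2 in HFD+AOS without HFD+AOS 11 and to 3 in HFD+AOS-FMT without HFD+AOS-FMT 5, from 23, 4 and 5 with all libraries; the cause was not tested.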

Other observations

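OTU1553 took a large share of reads in most, not all, libraries of the HFD groups; the libraries given here were picked after their values were seen. It held 18.5% ± 13.6 (SD, n = 10) of reads in HFD+AOS, 19.5% ± 13.5 (SD, n = 9) in HFD+AOS-FMT and 18.8% ± 14.9 (SD, n = 10) in HFD+control-FMT, against 6.58% ± 9.54 (SD, n = 10) in HFD, with adjusted p of 0.386, 0.213 and 0.223 in edgeR. In HFD it reached 24.4% in library 7 and 23% in library 5, was at 0.382% in library 11 and had no read in library 18. In HFD+AOS libraries 11 and 12 it was at 0.825% and 1.28%.

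OTU107 and OTU109 had reads only in treated HFD groups. OTU107 was found in 6 of 10 HFD+AOS and 5 of 9 HFD+AOS-FMT libraries and had no read in the other 4 groups, AOS included; HFD+AOS-FMT 14 held 95.7% of its HFD+AOS-FMT reads. OTU109 was found in 7 of 10 HFD+control-FMT libraries, with 1 read in HFD+AOS and none in the other 4 groups, control included. It was the single OTU with at least 10 reads in 5 libraries of HFD+control-FMT and at most 1% of its reads elsewhere; the same search gave 1 OTU for AOS and 0 for each of the other 4 groups. OTU109 ranged from 0.0159% to 1.35% of reads in the libraries that held it.

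The 254 OTUs found in at least 80% of control libraries in 1 random draw of 32134 reads per library were shared unevenly. In AOS, 199 of them were found in at least 80% of libraries, in HFD 116, in HFD+AOS 98, in HFD+control-FMT 94 and in HFD+AOS-FMT 73. With the 9 libraries of HFD+AOS-FMT, whole libraries reach 80% only at a larger share than in the other groups. The 73 was thus held to a stricter threshold. At 32134 reads, 62 of the 254 had no read in HFD+AOS-FMT, 26 in HFD+control-FMT, 35 in HFD+AOS and 19 in HFD. Such a count can drop through 1 control-like library. Of the 94 OTUs found in every control and AOS library, HFD+control-FMT 6 detected 84.6%. The 7 HFD and HFD+AOS libraries numbered above 10 detected 82.5% to 89.2%, and the highest HFD+AOS-FMT library 69.9%. The counts were not recomputed without these libraries, so they do not rank the 2 transfers.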
